A study of Drosophila melanogaster with 2 samples.

How the data were processed

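Chromatin immunoprecipitation sequencing (ChIP-seq) was performed on whole embryos of Drosophila melanogaster from a transgenic line carrying CG10654 fused to green fluorescent protein (GFP). Per the labels, the embryos were of both sexes and 0 to 24 h old, the antibody recognised GFP, and the chromatin had been sonicated to 200 to 800 bp. The samples form 1 group of 2 biological replicates, with no other condition, so no comparison between conditions was made. The aligner, the peak caller, the control of the error rate and all software versions are not given in the sources used here. The control library named by the authors' file descriptions was not analysed here.

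The deposited files are peak lists, not reads. The authors called candidate peaks in each replicate and in the pooled reads of both, each against a control library, per the file headers and descriptions. They then kept a shorter list by the irreproducible discovery rate (IDR), a method that compares the ranking of candidates between replicates. Peaks in this shorter list are called IDR peaks here. Every list was deposited in the dm6 and in the dm3 genome build. The deposited signal value (field 7) is the authors' enrichment per peak and has no absolute scale, so it was used to rank and filter peaks within a list. The deposited -log10 q value (field 9) is the authors' significance per peak. It was tied at the highest value for 2233 of the 4117 IDR peaks and was therefore not used for ranking. The candidate list of replicate 2 held 30000 entries in both builds, which may be a limit set by the authors and not a count of all candidates. The number of reads behind each list is unknown. The confidence intervals below are 95% Wilson intervals over peaks or genes and cover counting error only.

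On dm6 the authors' lists held 23253 candidates for replicate 1, 30000 for replicate 2, 27219 for the pooled reads and 4117 IDR peaks. The IDR list was exactly the top of the pooled list by signal value: 4117 pooled candidates lay at or above the lowest IDR signal of 99.3, and the highest remaining candidate had 99.3. A comparison of IDR peaks with the pooled candidates that did not pass is therefore a comparison of strong with weak candidates. The candidate lists are described by the authors as holding background as well as peaks.

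Coordinates were analysed on dm6, with the Release 6 genome sequence and the Ensembl release 115 annotation (FlyBase 6.54), over the arms 2L, 2R, 3L, 3R, 4 and X. Transposable element entries were left out, which left 18164 genes. A summit within 500 bp of an annotated transcription start site (TSS) was called a promoter summit. Other summits took the first of 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic that applied. All positions are 1-based. The dm3 lists were used for counts only, and no coordinate was converted between builds.

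Peaks were matched between lists when their summits lay within 100 bp. The share matched in both replicates, and the promoter share, were set against 1000 circular shifts along each arm (one-sided permutation tests, 100 shifts for alternatives). Signal values of matched peaks were compared by Spearman's rho and by Pearson's r on log2 signal, with 100000 permutations. Shares were compared with 2-sided Fisher's exact tests and adjusted by the Benjamini-Hochberg method over classes, arms or gene lists. GC content was taken over the summit and 50 bp on either side and tested by permutation of the difference of means, with 100000 resamples.

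The 28 gene lists and 22 consensus motifs were written from general knowledge before the data were examined, as were the tests and most of the alternatives. Some lists, such as the cytosolic ribosomal proteins, were defined by a name pattern and took the genes whose symbols matched it. Members of the other lists were matched by symbol, then by a RefSeq synonym belonging to 1 gene. 4 older names without such a match (RpII215, Dl, nos and calypso) were assigned to Polr2A, Delta, nanos and caly by hand, after the first list results had been seen. Without them, 9 lists lay above and 6 below the other genes, as with them. Each list was tested as members with an IDR promoter summit against all other annotated genes. A summit within 500 bp of the TSSs of several genes counted for each of them. All 8-mers, with both strands merged, were tested for presence in the summit window against a window of the same width centred 300 bp away, to the left and right in turn by rank, with exact McNemar tests. Words seen in 10 or more windows on 2L and 2R were tested first, and those found were tested again on the remaining arms. Consensus motifs were tested in the same way over all IDR peaks.

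Genes named in the text were chosen by a rule fixed before the data were examined. They are the genes with the nearest TSS, if within 1 kb, of the 20 IDR peaks of highest signal, with the partner gene at a divergent promoter. To these were added CG10654, the 4 members of highest promoter signal in each list past an adjusted p of 0.05, and up to 2 members of the other lists with 25 genes or fewer. Genes named outside that rule are said to be so. The alternatives varied the matching distance, the promoter window, the summit window, the word length, the control sequence, the background genes and the IDR list. To leave out a replicate, the IDR list was replaced by the 4117 strongest candidates of the other one. Added after the data had been seen were the feature classes among summits outside promoters, a direct match of the strongest candidates of both replicates, a control of dinucleotide-shuffled summit windows, a background of genes with no other gene's TSS within 1000 bp, and list members without the names assigned by hand.

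The tests were run on simulated data first. 8-mers planted in 3% of flank windows were recovered in 5 of 5 cases among 9715 words, and in 0 of 5 cases when planted in 1%. A gene list of 32 members was called in 100 of 100 simulations with a 4-fold share of peaks and in 22 of 100 with a 2-fold share. With peaks drawn at random over genes, 5 of 100 simulations called any of the 28 lists. Genes were drawn singly there, so this rate does not cover genes that share a peak or lie in clusters, which the list tests also treat as independent. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.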

Results

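The binding sites of CG10654, a gene whose product is described only as an uncharacterized protein, were mapped by ChIP-seq with an antibody against GFP in embryos expressing the tagged protein. Both replicates came from whole embryos collected over 0 to 24 h, so each value averages over all tissues and stages of embryogenesis. The authors' lists held 23253 candidates in replicate 1 and 30000 in replicate 2, a round number that may be a limit set by the authors, and 4117 IDR peaks, or 15.1% of the 27219 pooled candidates. The depth in reads is unknown. Signal values are the authors' own and carry no replicate error; the replicates' values are given where they bear on a peak.

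The first comparison asked how many IDR peaks had a matching summit in each replicate. IDR peaks were the strongest of the candidates called on the pooled reads of both replicates. This share and the agreement of signal below are therefore no independent test of the sites. The strongest site in the pooled data, at the promoter of Ugalt, which encodes a UDP-galactose transporter, ranked 1 in replicate 1 and 2 in replicate 2. The second, at CG14100, ranked 2 and 1. Of the 4117 IDR peaks, 3960 (96.2%, interval 95.6 to 96.7%) had a candidate summit within 100 bp in both replicates, and 3 had one in neither. Candidates shifted at random along the arms matched 0.155% of IDR peaks in both replicates on average and 0.413% at most (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Matched summits of the replicates lay a median of 22.0 bp apart. Of the pooled candidates that did not pass, 29.5% were matched in both. Against the 4117 strongest candidates of each replicate alone, 75.9% of IDR peaks were matched in both. Without the IDR list, 3115 of the 4117 strongest candidates of replicate 1 (75.7%, interval 74.3 to 76.9%) had a summit among the 4117 strongest of replicate 2, against 0.625% after shifting (permutation p = 0.000999), a comparison chosen after the data had been seen.

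Signal values of the replicates rose together over the matched IDR peaks, with Spearman's rho = 0.763 (bootstrap interval 0.747 to 0.778) and Pearson's r = 0.824 on log2 signal over 3960 peaks (permutation p = 1e-05 for each, adjusted p = 1.2e-05 over 6 such relations, the smallest that the permutations can give). Among pooled candidates that did not pass, rho was 0.408 over 6816 matched peaks. These relations run across peaks of a single pair of samples, and peaks are not independent replicates. Among the 2058 IDR peaks of highest pooled signal rho was 0.756. Among the other IDR peaks, which span a narrow band of pooled signal, it was -0.0128 (permutation p = 0.575). Pearson's r was -0.0616 there (adjusted permutation p = 0.00675). Pooled signal lay near the replicates' values added together, as at Ugalt (1720 and 776, pooled 2484). Within a narrow band, a peak higher in 1 replicate therefore tends to be lower in the other. That selection lowers both values, so they cannot show whether the replicates agree on these peaks.

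**Figure D1:**
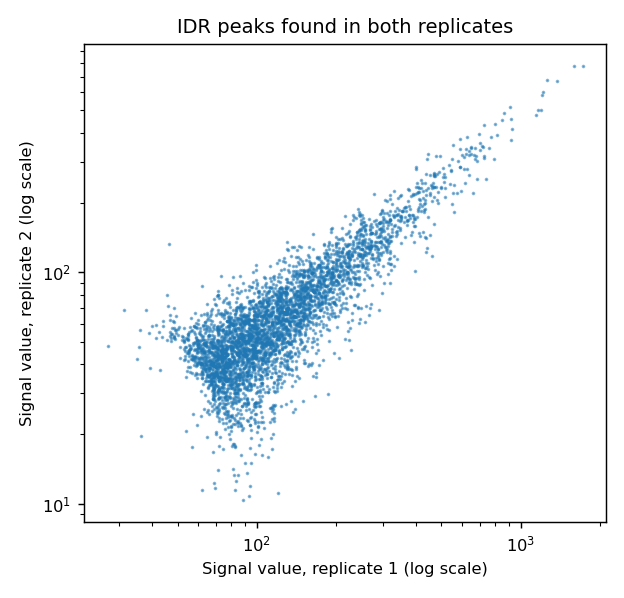
Signal value of each IDR peak matched in both replicates, with replicate 1 on the x axis and replicate 2 on the y axis, both on log scales. Each of the 3960 points is 1 peak, and the points scatter less towards the strongest peaks (Spearman's rho = 0.763).

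Most of the 20 strongest peaks had their summit within 500 bp of a TSS. The peak of highest signal (2484) spanned positions 2703687 to 2704097 of the X chromosome, with its summit 23 bp upstream of the Ugalt TSS. The reference sequence at that summit and 50 bp on either side read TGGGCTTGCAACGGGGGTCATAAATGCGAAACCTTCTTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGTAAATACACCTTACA, of which 35.6% was G or C. The peak at CG14100 (3L, 19590430 to 19590808, signal 2364) had its summit 102 bp upstream of the TSS. The wing vein gene px carried a peak on 2R from 22514113 to 22514500 (signal 1944), 200 bp upstream. The mitochondrial ribosomal protein gene mRpL41 carried one on 2R from 15217562 to 15217955 (signal 1809), 138 bp upstream. Next among promoters came the Polycomb group gene ph-p (X, 2137178 to 2137555, signal 1669), with a summit 491 bp upstream of its TSS. A peak on 3L from 22878703 to 22879101 (signal 1662) had its summit 87 bp downstream of a TSS of Chro, which encodes the chromatin protein Chromator, and within 500 bp of that of Ssl1, which encodes a subunit of the transcription factor TFIIH.

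Several of the other leading peaks lay between gene pairs. Art3, an arginine methyltransferase gene, and mRpS10 shared the peak on 3R from 15229351 to 15229709 (signal 1619). Tcs5 and the ESCRT gene CHMP2B shared 1 on 3L (signal 1338), and CenG1A and mRpS23 shared 1 on 2L (signal 1311). Single promoter peaks lay at PNPase, which encodes a mitochondrial RNA-degrading enzyme (signal 1379), at lncRNA:CR31840 (1342), at CG1888 (1228) and at CG18549 (1156). The summits nearest to the kinase gene Lk6, to lncRNA:CR45643 and to the HMG-box gene HmgZ lay 958, 907 and 555 bp upstream of a TSS. Those at Lk6 and HmgZ were intronic and that at lncRNA:CR45643 was intergenic. Each of the 20 strongest peaks ranked 23 or better in replicate 1 and 29 or better in replicate 2.

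The next comparison asked where IDR peaks lie relative to genes. Promoters took 2164 of the 4117 IDR peaks (52.6%, interval 51.04 to 54.08%), against 26.2% of the pooled candidates that did not pass (odds ratio 3.13, Fisher's exact p = 3.15e-235). Peaks shifted along the arms gave 13.6% on average and 16.2% at most (permutation p = 0.000999, the smallest possible), so the observed share was 3.88 times the shifted one. In all, 2969 of 18164 annotated genes (16.3%) had an IDR promoter summit, among them 2763 of 13945 protein-coding genes (19.8%) and 173 of 3261 long or other non-coding RNA genes (5.31%).

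Summits lay just upstream of the start site. Of the 2164 promoter summits, 1852 (85.6%, interval 84.0 to 87.0%) were upstream of the nearest TSS, at a median signed distance of -108.5 bp and with quartiles of -192.0 and -45.0 bp. Among promoter candidates that did not pass, 62.0% were upstream, at a median of -49.0 bp (odds ratio 3.65, Fisher's exact p = 2.56e-100). Divergent promoters, with a TSS on each strand pointing away from the summit, held 852 promoter IDR summits (39.4%, interval 37.3 to 41.4%) and 14.3% of those that did not pass (odds ratio 3.88, Fisher's exact p = 2.75e-122). The tests of side and of divergence were chosen after the data had been seen.

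**Figure D2:**
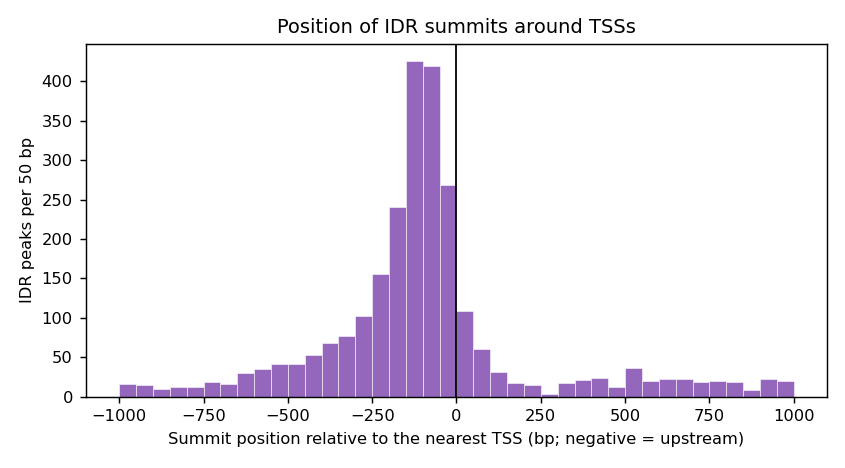
Number of IDR peaks per 50 bp (y axis) by position of the summit relative to the nearest TSS in bp (x axis, negative is upstream). The bars pile up on the upstream side, where 85.6% of the summits within 500 bp lay.

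Coding sequence was almost free of IDR peaks. Only 6 of 4117 summits (0.146%) fell in coding exons outside promoters, against 5.67% of the candidates that did not pass (odds ratio 0.0243, Fisher's exact test, adjusted p = 9.34e-85 over 7 classes). The 3' UTRs held 0.680% against 3.61% (odds ratio 0.183, adjusted exact p = 1.13e-30) and 5' UTRs 0.437% against 0.948% (odds ratio 0.459, adjusted exact p = 0.000806). Introns held 1354 IDR summits, or 32.9% against 42.1% (odds ratio 0.675, adjusted exact p = 1.29e-28), and intergenic sequence 12.3% against 20.6% (odds ratio 0.540, adjusted exact p = 3.41e-38). Other exons, those of non-coding transcripts, did not pass the test (adjusted exact p = 0.792). These shares add up to a fixed total, so a higher promoter share lowers the others. The classes were therefore compared again among summits outside promoters, after the data had been seen. Introns then turned the other way, with 69.3% of 1953 IDR summits against 57.0% of 17057 weak candidates (odds ratio 1.71, Fisher's exact test, adjusted p = 5.25e-26 over 6 classes). Intergenic sequence (26.0% against 27.9%, adjusted exact p = 0.0787) and 5' UTRs (adjusted exact p = 0.196) did not pass. Coding exons (odds ratio 0.0370, adjusted exact p = 1.1e-53) and 3' UTRs (odds ratio 0.283, adjusted exact p = 7.58e-15) stayed lower, and other exons passed as higher (odds ratio 1.65, adjusted exact p = 0.00971).

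Chromosome 4, the small and largely heterochromatic chromosome, carried 15 IDR peaks, or 11.1 per Mb. The other arms carried between 28.8 per Mb on 2R and 32.7 per Mb on 2L. Its share was 0.364% of IDR peaks and 1.40% of candidates that did not pass (odds ratio 0.257, Fisher's exact test, adjusted p = 2.2e-09 over 6 arms). The right arm of chromosome 3 held slightly more IDR peaks than weak candidates (24.8% against 23.1%, odds ratio 1.10, adjusted exact p = 0.0465). That call was lost without replicate 2 (odds ratio 1.02, adjusted exact p = 0.588) and among the 2058 strongest IDR peaks (odds ratio 1.07, adjusted exact p = 0.426). The X chromosome passed the test only without replicate 2 (odds ratio 1.13, adjusted exact p = 0.0281).

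Genes of the cytosolic ribosome carried promoter peaks far more often than other genes. Of 86 cytosolic ribosomal protein genes, 66 (76.7%, interval 66.8 to 84.4%) had an IDR promoter summit, against 16.1% of all other genes (odds ratio 17.3, Fisher's exact test, adjusted p = 1.08e-33 over 28 lists). The name pattern behind this list missed RpL37-1, named here outside the rule. It had an IDR promoter summit (signal 170) and counted among the other genes. The strongest lay at RpS27 (3R, 25247369 to 25247671, signal 889), RpL7 (2L, 10200896 to 10201167, signal 594), RpL23A (3L, 1668603 to 1668900, signal 573) and RpL34b (3R, 9401162 to 9401505, signal 549). Replicate 1 gave these genes more weight than replicate 2 did: among the 4117 strongest candidates of each, 80.2% of the list had a promoter peak from replicate 1 (odds ratio 20.9) and 57.0% from replicate 2 (odds ratio 7.26). Over the 68 matched peaks at these promoters, 64 had a higher percentile rank in replicate 1 than in replicate 2, a comparison chosen after the data had been seen.

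Mitochondrial ribosomal protein genes had peaks at 29 of 73 promoters (39.7%, odds ratio 3.40, Fisher's exact test, adjusted p = 5.25e-06). Of the 13 with no neighbouring promoter 2 had one, and the call was lost there (odds ratio 2.00, adjusted exact p = 0.535). After mRpL41, mRpS10 and mRpS23, named above, the strongest was mRpL23 (3L, 2373446 to 2373789, signal 934). Other lists of metabolic and protein-handling genes did not pass. Oxidative phosphorylation genes had peaks at 18 of 84 promoters (adjusted exact p = 0.293), proteasome subunit genes at 11 of 48 (adjusted exact p = 0.293) and translation initiation factor genes at 11 of 44 (adjusted exact p = 0.220). Translation initiation factors passed with a 250 bp promoter window (adjusted exact p = 0.0434) and without replicate 1 (adjusted exact p = 0.0390). The heat shock list had 7 of 25 (adjusted exact p = 0.235), with signals of 729.9 at Hsp27 and 408 at Hsp83.

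Genes for chromatin and transcription proteins passed as well. In the list of insulator and architectural protein genes, 9 of 19 had a promoter peak (47.4%, odds ratio 4.62, Fisher's exact test, adjusted p = 0.00402). They were led by Chro, by Cp190, which encodes an insulator cofactor (3R, 15275191 to 15275552, signal 611), and by M1BP and Dref, which encode core promoter binding proteins (signals 317 and 266). The peak at Dref is also that of the cytosolic ribosomal protein gene RpL13, named outside the rule for sharing it. Only 3 genes of this list have no neighbouring promoter, and 0 of them had a peak (odds ratio 0.0, adjusted exact p = 1.0), so the list says little of promoters that stand alone. The Polycomb and Trithorax group list had 10 of 23 (odds ratio 3.95, adjusted exact p = 0.00420). Its leading members were ph-p, the chromatin remodeller gene brm (3L, 15982856 to 15983168, signal 625), the histone methyltransferase gene E(z) (signal 411) and Sfmbt (signal 209.8). Core transcription genes had 10 of 23 (odds ratio 3.95, adjusted exact p = 0.00420), led by Polr2B, which encodes a large RNA polymerase II subunit (signal 449.5), and by the TFIID subunit genes Taf5, Taf2 and Taf4 (signals 360, 263 and 253). The core transcription call was lost without replicate 1 (odds ratio 2.37, adjusted exact p = 0.133). The peaks given for M1BP, Taf5 and Taf2 lay nearest to the TSS of another gene.

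Cell cycle genes had peaks at 16 of 33 promoters (48.5%, odds ratio 4.84, Fisher's exact test, adjusted p = 5.48e-05). The highest were at Dp, the partner of E2F (signal 425), at the cyclin gene CycE (signal 282), at the replication helicase gene Mcm2 (signal 219.8) and at the mitotic kinase gene aurA (signal 191). Housekeeping genes had 9 of 19 (odds ratio 4.62, adjusted exact p = 0.00402), with Gapdh2 first (signal 754), then eEF1alpha1 (276), Rack1 (221) and eEF2 (204.6). Signalling genes had 11 of 33 (odds ratio 2.56, adjusted exact p = 0.0289). They were led by spi, which encodes a ligand of the EGF receptor (signal 548), and aos (333), then InR, the insulin receptor gene (205.4), and hpo, the Hippo kinase gene (197). Germline marker genes had 7 of 16 (odds ratio 3.99, adjusted exact p = 0.0180), led by bgcn (386), gcl (172), Sxl (171) and vas (147). The peaks at CycE and gcl had no candidate summit within 100 bp in replicate 2. Those given for gcl and vas lay nearest to the TSS of another gene. The signalling call was lost without replicate 2 (odds ratio 2.20, adjusted exact p = 0.103) and the germline call without replicate 1 (odds ratio 2.46, adjusted exact p = 0.146), so the direction stayed in each. Both were also lost with a 250 bp promoter window (odds ratios 1.23 and 3.13, adjusted exact p = 0.680 and 0.0803) and among protein-coding genes (odds ratios 2.03 and 3.15, adjusted exact p = 0.121 and 0.0552). Among genes with no neighbouring promoter, the cytosolic ribosomal, Polycomb and Trithorax, cell cycle and signalling lists kept their calls. Against genes with a pooled candidate at the promoter, the cytosolic ribosomal list was the only 1 of the 9 that kept its call (odds ratio 8.52, adjusted exact p = 3.78e-16), while the other 8 had odds ratios from 1.08 for signalling to 6.21 for germline genes (adjusted exact p = 0.0625 for the latter). Among the 2058 strongest IDR peaks the calls for mitochondrial ribosomal (odds ratio 2.11, adjusted exact p = 0.0548), housekeeping (3.47, adjusted exact p = 0.0584), cell cycle (2.16, adjusted exact p = 0.199) and germline genes (2.24, adjusted exact p = 0.285) were lost.

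Genes for cuticle proteins, chemosensory receptors, histones, tRNAs, microRNAs and small nucleolar RNAs had IDR summits near an annotated TSS less often than other genes. The TSS was the 5' end of each annotated transcript. For microRNA and small nucleolar RNA genes that end need not be where transcription starts. Their shares therefore do not measure peaks at the promoters that drive them. None of 121 cuticle protein genes had one (upper bound of the interval 3.08%, Fisher's exact test, adjusted p = 3.23e-09). Of 185 chemosensory receptor genes 1 had, Ir60e (signal 139.8, odds ratio 0.0275, adjusted exact p = 3.71e-12), a call lost among genes with a pooled candidate (1 of 14, adjusted exact p = 0.0980). Peaks lay at 13 of 295 tRNA genes (4.41%, odds ratio 0.233, adjusted exact p = 1.95e-09), the strongest at tRNA:Tyr-GTA-1-8 (signal 538), tRNA:His-GTG-1-3 (240.3), tRNA:Phe-GAA-1-2 (239.6) and tRNA:Trp-CCA-2-2 (220.3). They lay at 7 of 260 microRNA genes (2.69%, odds ratio 0.140, adjusted exact p = 1.91e-11), led by mir-9378 (420.2), mir-9377 (299), mir-ban (139.7) and mir-966 (131). Of 257 small nucleolar RNA genes 13 had a peak (5.06%, odds ratio 0.269, adjusted exact p = 1.63e-07). The strongest lay within 500 bp of snoRNA:Or-aca5 and snoRNA:Psi28S-2949 (signal 522), but nearest to the TSS of another gene. It was followed by those at snoRNA:Or-CD11a (434) and snoRNA:U49:66Da (395). The peaks at snoRNA:Or-CD11a, snoRNA:U49:66Da and tRNA:Phe-GAA-1-2 are those of the ribosomal protein promoters of RpL28, RpL14 and RpL17, genes named outside the rule for sharing those peaks. Among 116 histone genes the peaks were at His2Av and His3.3B (signals 267 and 144), genes of replication-independent variants (odds ratio 0.0892, adjusted exact p = 1.73e-06). The direction of the histone list turned among genes with a pooled candidate, as given below. The peaks given for His2Av, Ir60e, tRNA:Trp-CCA-2-2, mir-9377 and mir-ban lay nearest to the TSS of another gene. Histone and tRNA genes have many near-identical copies, and reads from such copies cannot be placed with certainty. Without replicate 1 the odds ratio was 0.258 for microRNA and 0.0466 for histone genes, and with a 1000 bp promoter window the call for small nucleolar RNA genes was lost (adjusted exact p = 0.736). Most of these lists did not pass among genes with no neighbouring promoter.

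The lists of patterning genes and of tissue markers other than germline did not pass in either direction. Early segmentation genes had 1 promoter peak in 22, at bcd (signal 169), dorsoventral patterning genes 0 in 17 (adjusted exact p = 0.155) and homeotic genes 1 in 8, at Dfd (signal 100.2). Neural markers had 1 in 26 (adjusted exact p = 0.170) and hemocyte markers 0 in 16 (adjusted exact p = 0.155). Muscle markers had 6 in 25, with the highest signals at Msp300 (564) and mbc (277). The peak given for mbc lay nearest to the TSS of another gene. The midgut and fat body list had 4 in 17, of which the ferritin genes Fer2LCH and Fer1HCH shared 1 peak (signal 492). The epidermis and trachea list had 3 in 18, with the highest at trh (238) and pck (144). Small nuclear RNA genes had 4 in 32. With lists this short, an absence of a call leaves wide intervals, such as 0 to 18.4% for dorsoventral genes.

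**Figure D3:**
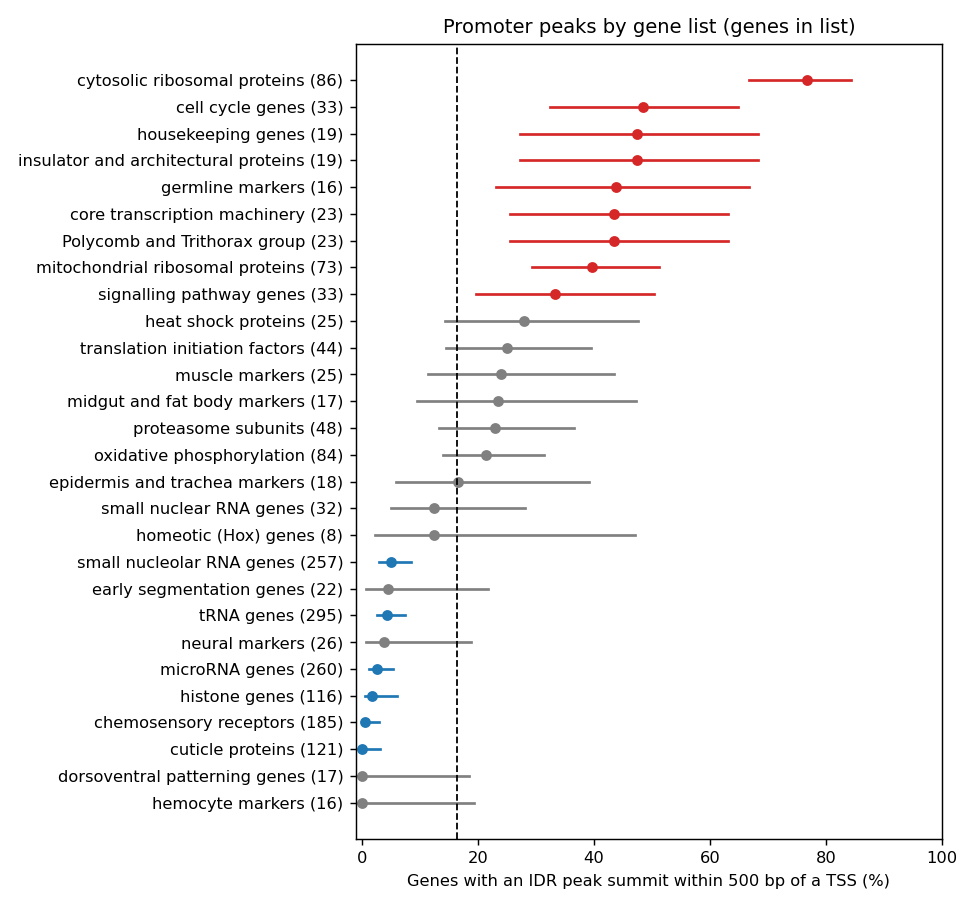
Percent of the genes in each list with an IDR summit within 500 bp of a TSS (x axis), with 95% Wilson intervals and the number of genes in brackets; the dashed line is the 16.3% of all annotated genes. Red lists lay above and blue lists below the other genes at an adjusted p under 0.05, grey lists did not pass, and cytosolic ribosomal protein genes stood highest at 76.7%.

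The base composition of the peaks was compared with that of weak candidates and of the surrounding DNA. Summits of IDR peaks were rich in A and T: the median GC content within 50 bp of them was 31.7%, against 39.6% in candidates that did not pass. The means were 33.3% ± 8.95 (SD, n = 4117) and 39.5% ± 10.2 (SD, n = 23102), a difference of -6.20 percentage points (permutation p = 1e-05, the smallest possible). The same peaks' flanks 300 bp away averaged 43.9%, and the 6 arms as a whole 42.2%. GC content was lower at the summit than in the flank at 77.3% of IDR peaks. Summits outside promoters averaged 32.7% and those at promoters 33.9%. Peaks at cytosolic ribosomal protein promoters differed, with a mean of 44.8% over 68 peaks against 33.5% over 2001 other promoter peaks (permutation p = 1e-05, adjusted p = 0.0001 over 10 lists, chosen after the data had been seen).

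**Figure D4:**
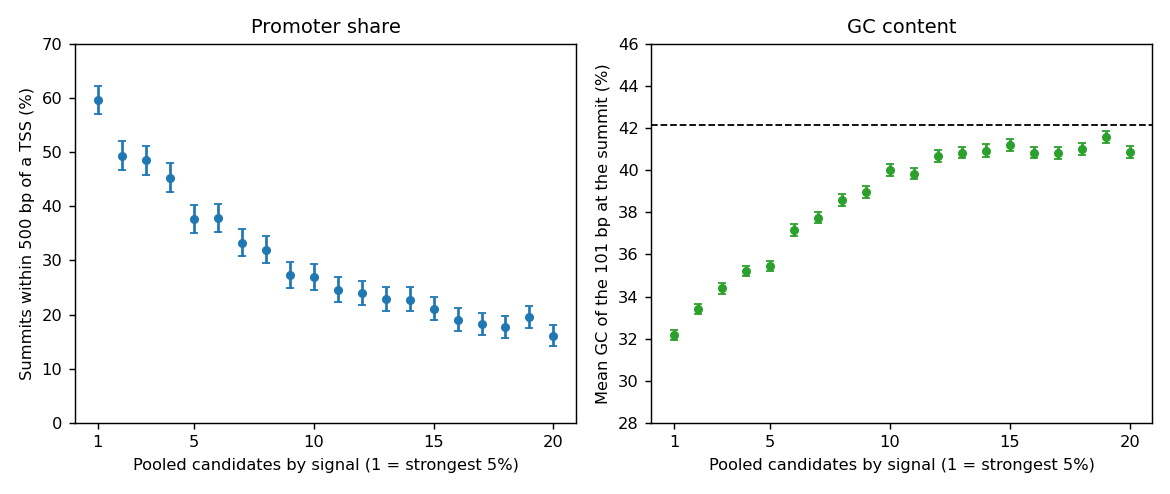
Pooled candidates in 20 bins of falling signal (x axis, bin 1 is the strongest 5%), with the percent of summits within 500 bp of a TSS and 95% Wilson intervals (left) and the mean GC percent within 50 bp of the summit with standard errors (right; the axis does not start at 0, and the dashed line is the mean of the arms, 42.2%). The promoter share fell from 59.7% in bin 1 to 16.0% in bin 20, while mean GC rose from 32.2 to 40.9%.

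Sequence words at the summits were sought next. Against their own flanks, 257 of 8882 8-mers were found more often at summits on 2L and 2R and 92 less often (exact McNemar tests, adjusted p under 0.05), and 223 of the 257 passed again on the other arms. Of the 257, 248 held at most 25% G or C. Among 6-mers the balance turned, with 337 of 2079 above and 617 below, and 208 of the 337 held at most 25% G or C. The word of smallest p was TTTAAAAA, present in 104 summit and 27 flank windows on the first arms and in 170 and 62 on the others (adjusted exact p = 6.6e-08 and 3.27e-12). No word passed when left and right flanks were compared with each other (0 of 9714, with 247 at an unadjusted p under 0.05). Against weak candidates matched on promoter status, 1 8-mer passed on the first arms and 0 on the others, beside 681 of 8577 words at an unadjusted p under 0.05.

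Against the same windows with bases shuffled, a control added after the data had been seen that keeps dinucleotide counts, 13 words passed and 12 of them passed again on the other arms. They included 8-mers of the DNA replication-related element (DRE), the site of Dref. The word ATCGATAG was present in 29 windows against 1 on 2L and 2R and in 56 against 2 elsewhere (exact McNemar test, adjusted p = 0.000481 and 1.49e-13). CACTGAGA was present in 25 against 1 and in 31 against 4, CAACACTG in 28 against 4 and in 42 against 4, and CAGCCCTG in 19 against 2 and in 25 against 3. Each of these occurred in a few percent of peaks at most.

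Of the 22 known motifs, 9 were more frequent at summits than in flanks and 5 less frequent. The DRE (TATCGATA) was present at 75 of 4117 summits (1.82%, interval 1.46 to 2.28%) and in 17 flanks (exact McNemar test, adjusted p = 3.21e-09), and against shuffled windows in 75 and 2 (adjusted p = 8.76e-19). Against weak candidates matched on promoter status, where it was present in 1.65%, the call was lost (adjusted exact p = 0.749). It was found at 3.37% of promoter peaks and 0.102% of other peaks (Fisher's exact test, adjusted p = 2.24e-17). The strongest DRE peak lay at Alg3 (2R, 23709727 to 23710017, signal 745), a gene named outside the rule after its value was seen. The CGATA element of BEAF-32 was present at 16.7% of summits and 12.6% of flanks (adjusted exact p = 3.16e-07). TATCGATA contains CGATA, so each window with a DRE was counted here too and the 2 calls are not independent. The CGATA call was lost among the 2058 strongest peaks (14.1% against 12.6%, adjusted exact p = 0.245). The M1BP motif was present at 0.753% of summits and 0.364% of flanks (adjusted exact p = 0.0418). For M1BP the ratio of summits to flanks was 2.07, and its call was lost without replicate 1 (ratio 1.92, adjusted exact p = 0.107) and without replicate 2 (ratio 1.56, adjusted exact p = 0.309). Against weak candidates matched on promoter status the M1BP motif was present in 31 and 48 (ratio 0.646, adjusted exact p = 0.199), so its direction turned without passing. Against shuffled windows it was present in 31 and 0 (adjusted exact p = 5.12e-09). The GAGA factor motif was less frequent at summits than in flanks (1.04% against 3.45%, adjusted exact p = 3.38e-13) but more frequent than in shuffled windows (43 against 13, adjusted exact p = 0.000323). AT-rich motifs such as TAATTA, the core of homeodomain sites, turned the other way: 9.98% at summits against 5.34% in flanks (adjusted exact p = 1.24e-14), but 12.1% in shuffled windows (adjusted exact p = 0.00495).

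The locus of the tagged gene was examined in case the transgene adds a copy of it, which the labels do not say. CG10654 (FBgn0036294, 3L, 12505374 to 12507840, minus strand) had no IDR peak at its own promoter. The single pooled candidate within 500 bp of its TSS had a signal of 34.6, rank 17571. Within 10 kb lay 4 IDR peaks, at the divergent promoters of vih and CG10646 (12504013 to 12504402, signal 264) and of CG10681 and CG10638 (12501283 to 12501672, signal 182), near sti and tral (12514753 to 12514978, signal 323), and in an intron of CG10657 (12495373 to 12495762, signal 139.8). These neighbours are named for their position. As many IDR peaks lay within 10 kb of 6.33% of annotated genes, and as strong a peak within 10 kb of 16.1%. As many pooled candidates (10) lay within 10 kb of 19.6%.

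The last comparison set the genome builds side by side. The IDR list held 3848 peaks on dm3 and 4117 on dm6, a ratio of 0.935. Ratios per arm ran from 0.917 on 3R to 0.954 on X, and chromosome 4 had 15 peaks on both. The pooled list held 24762 and 27219 candidates. The highest signal was 2484 on both builds, and the 20 highest values differed by at most 0.0394% rank for rank.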

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

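The dm3 lists contain candidates on sequences outside the 6 arms, which enter the totals compared between builds and no other comparison. In the pooled dm3 list, 80 candidates lay on such heterochromatin and unplaced sequences, above the limit of 3 that a count of 0 allows. Of these, 32 were on the unassembled heterochromatin of 3L and 17 on that of 2R. Only 1 of them, on 2RHet, was an IDR peak. The dm6 lists used here hold peaks on the 6 arms alone.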

How the results depend on the processing

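The share of IDR peaks matched in both replicates (75.7 to 99.7%, the lowest from the direct comparison of the replicates chosen after seeing the data), the promoter share (42.4 to 62.8%), and the GC difference (-7.06 to -4.60 points) kept their direction and call under every alternative run. So did the number of feature classes past the threshold, except that among summits outside promoters, an alternative chosen after seeing the data, 4 passed and introns turned to an odds ratio of 1.71. Each replicate was left out in turn for all of these but the first. Replicate agreement turned to -0.0128 among the IDR peaks below the 2058 strongest, a narrow band of pooled signal, a selection that by itself lowers the value. Among the 2058 strongest, 1 arm (chromosome 4) passed in place of 2. The ratio of dm3 to dm6 IDR peaks was 0.934 on the 6 arms. Within 2 kb and 50 kb of CG10654 lay 1 and 11 IDR peaks.

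Of the 9 gene lists above the other genes, 5 passed among the 2058 strongest peaks, 1 among genes with a pooled candidate and, in a background chosen after seeing the data, 4 among genes with no neighbouring promoter. Of the 6 below, 3 passed among protein-coding genes, where RNA genes are not counted, and 2 among genes with no neighbouring promoter. There the insulator list had an odds ratio of 0.0, and histone genes had 1.77 among genes with a pooled candidate, where the chemosensory call was lost as well (adjusted exact p = 0.0980). Over single lists, classes, arms and motifs, 354 alternative values stayed on their side of the threshold, 59 lost it, 8 gained it and 12 turned direction. The cause was not tested.

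Words above and words that passed again on other arms (257 and 223) came to 1 and 0 against matched weak candidates, 60 and 47 within 25 bp of the summit, 471 and 412 within 100 bp, 149 and 122 in the 2058 strongest peaks, 337 and 306 for 6-mers, 39 and 24 for 10-mers, and 13 and 12 against shuffled windows, an alternative chosen after seeing the data. Words below (92) came to 617 for 6-mers, the only setting where they outnumbered words above, and to between 0 and 196 otherwise. Known motifs above and below (9 and 5) came to 3 and 2 against matched weak candidates and 4 and 2 within 25 bp; 5 lay above in the 2058 strongest peaks and 2 below against shuffled windows. Against matched weak candidates the ratio was 0.646 for M1BP and 1.0 for Ohler 6. Against shuffled windows it was 3.31 for the GAGA factor, 1.17 for the TCT initiator, 1.24 for Zeste, 0.920 for the TATA box, 0.972 for the initiator, 0.875 for GATA and 0.824 for TAATTA. With 0 shuffled windows no ratio could be given for CLAMP, below the flanks but present at 11 summits (adjusted exact p = 0.00307), which the counts leave out. Shuffled windows share the composition of the summits and flanks do not. The depth of the libraries is unknown, which leaves open how many weaker sites were missed.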

Other observations

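Of the tests in this part, those of peak width, GC and rank by gene list, of ubiquitously expressed genes, of replicate ranks against other promoter peaks, of windows of 28 to 38% GC and of motifs at the strongest peaks were chosen only after the result was seen. Peaks at cytosolic ribosomal protein promoters differed from other promoter peaks in width, base composition and replicate rank. Of 68 such peaks, 47.1% were narrower than 300 bp, against 27.1% of 2001 other promoter peaks (Fisher's exact test, adjusted p = 0.00784 over 10 lists). Width depended on signal, as 95.3% of all pooled candidates but 69.6% of IDR peaks were 390 bp wide. The comparison of widths was not matched on signal. Their summits averaged 44.8% GC. Their mean percentile rank among matched IDR peaks was 66.3 in replicate 1 and 45.6 in replicate 2. None of the other 9 lists with 10 or more matched peaks passed the permutation test of rank between the replicates (lowest adjusted p = 0.261, tRNA genes), and the mitochondrial ribosomal list differed from other promoter peaks by 1.85 percentile points (interval -5.30 to 10.2).

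The frequency of peaks at cytosolic ribosomal protein promoters (76.7%) was weighed against 3 technical explanations. Base composition at 1 fixed distance upstream of the TSS is argued against: protein-coding genes matched on GC there had a promoter peak in 25.02% of cases. The ribosomal protein genes averaged 34.1% GC at that distance and 44.8% at their peak summits, so composition at the summits was not matched. A signal shared by all ubiquitously expressed genes is argued against only as far as the lists compared stand for such genes. Of oxidative phosphorylation, proteasome and translation initiation genes, 22.7% had a promoter peak (interval 17.2 to 29.5%), and 30.1% with 3 more such lists added (25.1 to 35.6%). Members of the first 3 lists were matched by name pattern, so not all need be ubiquitously expressed. The housekeeping list alone (47.4%, 27.3 to 68.3%) leaves room for a signal at some such genes. An unspecific signal at the most highly transcribed promoters that differs between the replicates stays open: the 18.6 percentile points by which these peaks ranked higher in replicate 1, relative to other promoter peaks (interval 13.97 to 23.27), prompted it and so cannot count in its favour. No expression data and no immunoprecipitation without the tag were used here, so binding by CG10654 and such a signal stay open, and no biological explanation was tested.

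The higher rank of these peaks in replicate 1 could also come from a GC-dependent difference between the libraries. Other promoter peaks matched on summit GC ranked 4.38 percentile points higher in replicate 1, and the ribosomal protein peaks exceeded them by 16.4 points (interval 11.3 to 21.2), which argues against GC as the whole cause. A difference between the embryo collections was not tested.

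The AT-rich summits of the IDR peaks were weighed against 2 technical explanations. The base composition of promoters is argued against only as far as protein-coding genes without a candidate stand for promoters in general. Promoter IDR summits lay at -6.60 percentage points relative to the same distances from TSSs of such genes (33.9 against 40.5%, standard error 0.302). These genes were selected for lack of signal. All protein-coding genes other than cytosolic ribosomal protein genes averaged 37.2% GC at a fixed distance upstream, nearer to the summits. That value was not matched on distance, so the size of the gap to promoters in general was not tested. A library bias towards AT-rich DNA as all that places the peaks is also argued against, since among genome windows of 28 to 38% GC the rate of IDR summits inside promoters was 6.18 times that outside (interval 5.61 to 6.80). That test was chosen when the promoter share was known and does not show whether the library lowers the GC of summits at bound sites. Such a bias stays open, as the control library was not analysed here, and no biological explanation was tested.

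It was also asked whether the DRE, M1BP and CTCF-core motifs are rarer at the 411 strongest IDR peaks. They were present at 23 of these (5.60%) and at 241 of 3706 others (6.503%), an odds ratio of 0.852 (Fisher's exact p = 0.526), so no difference was shown. Among promoter peaks the shares were 5.82 and 8.68% (odds ratio 0.650, Fisher's exact p = 0.128). Of 22 motifs tested singly, the BEAF-32 element differed, at 11.4% of the strongest and 17.3% of the other peaks (adjusted exact p = 0.0464).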
